A study of Mus musculus with 20 samples.

How the data were processed

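Expression was measured in 20 mouse melanoma samples of 2 genotypes and 3 compartments, as complete tumors and as CD45+ and CD45- cells. Per the labels' protocols, melanocytic recombination was induced by 4-hydroxytamoxifen on the skin (5 mg/ml) in pups aged 2.5 and 3.5 days, followed by a single UVB dose of 6.24 kJ per square meter, and tumors were taken at endpoint size. Per the labels' protocols, sorted samples were dissociated mechanically and with enzymes and separated with a magnetic CD45 positive selection kit, RNA was purified on Direct-Zol columns and checked for integrity, and cDNA made with the WT PLUS kit was labeled with biotin. The deposited values are log2 expression values that the authors obtained with RMA, per the submitters' processing notes, which give no version. Background correction, normalization and summarization of probes were therefore complete before deposition, and which arrays were normalized together is not given in the sources used here. The platform's genome build is not named, so no coordinates are reported.

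The deposited table had 21244 rows with values from 1.31 to 14.15 and 0 missing values. It held 0 columns of other samples. The platform annotation paired 19570 rows with 1 gene symbol, 0 with several and 1674 with none, and those are unnamed here. All 19570 names matched a RefSeq gene of GRCm38.p6 by entrez number, and 0 symbols changed. Where a gene had more than 1 row, the row with the highest mean over all arrays was kept, which left out 66 rows and gave 19504 genes. RefSeq was used otherwise only for which measured genes neighbor each other. No filter on dim genes was applied. No depth applies to arrays, and their number limits the precision.

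Groups were taken from the sample labels. Within each compartment the genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 over all genes. Differences are B;p38α minus B on the log2 scale. CD45+ and CD45- populations were compared over the 4 sorted groups, and interaction contrasts asked whether a genotype difference differed between compartments. The 47 gene lists, with 808 entries and 729 distinct genes of which 668 were measured, covered cell types of skin, tumor and blood, signaling through p38 and ERK, inflammation, antigen presentation, proliferation, matrix and metabolism. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 47 lists. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Mapk14 was also compared with a two-sided exact permutation test. Correlations of genotype differences across genes were set beside 100 relabelings of genotype within compartments. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

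Tests, groups, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule named Mapk14 and up to 12 genes each way with the largest difference among those past the threshold. Where fewer passed, names were filled up to 8 each way with the largest differences at an unadjusted p under 0.01 without overlap of the groups, and these are described as not passing. From each described list it named 2 to 4 members with the largest differences, to which members that passed within a list were added. For the sorted populations it named the 8 largest each way. A single genotype difference over all 20 arrays with compartment as a covariate was added after the genotype comparisons had been seen, as were a fit without the 2 arrays of narrowest range and a fit that averaged the 2 most similar arrays.

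The tests were tried on simulated arrays with 19504 genes and known changes. At a log2 change of 1 the test recovered 43% of 100 changed genes in complete tumors, 26% in CD45+ and 0% in CD45- populations, and at a change of 2 it recovered 93%, 74% and 44%, with 12, 7 and 3 false calls. For CD45+ against CD45- it recovered 66% and 90%, for the interaction of the sorted populations 4% and 54%, and over all 3 compartments 85% and 100%. Camera recovered 5 of 5 lists shifted by 0.5 in each compartment with 0 false lists, on genes simulated as independent, so it says nothing about correlated genes.

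Alternatives were all 6 groups in a single fit, the replicate number as a block, leaving out genes under the 30th percentile of mean level, repeated quantile normalization, array weights, every row of the table, the mean of 3 measured Y-linked genes as a covariate, a trended robust variance, and leaving out each array in turn. Other splits of the samples were enumerated within compartments, and 100 relabelings were drawn for the remaining contrasts. For those over all 20 arrays more than 1 draw was made, and the draw with the highest counts is the one reported. The sex of the animals is not given in the labels. Raw scanner data were not used here.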

Results

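Gene expression was measured on 20 microarrays of mouse melanomas of 2 genotypes. In both, tamoxifen-driven Cre recombinase active in melanocytes switched on the oncogenic kinase BRAF V600E, and newborn skin was irradiated once with UVB. In the line called B this was the only recombined gene, and in the line called B;p38α the gene of the stress-activated kinase p38α, Mapk14, was deleted as well. RNA came from complete tumors (5 B and 3 B;p38α samples), from cells selected with magnetic beads for CD45, the surface protein of leukocytes (CD45+, 3 and 3), and from the remaining tumor and stromal cells (CD45-, 3 and 3). Each array gave log2 values for 19504 named genes, with array medians from 6.78 to 6.98. Their number, between 3 and 5 per group, limits the precision of every difference below. The labels call the samples biological replicates without saying whether each came from its own animal, so p-values measure the spread between these samples, part of which may be technical. B CD45- replicate 1 stood apart, with an interquartile range of 2.95 against 3.40 to 3.89 in the other arrays and a median correlation of 0.911 with its own group. The mean level of the 3 measured Y-linked genes lay between 8.60 and 9.29 in B complete replicates 1 and 4, B CD45+ replicate 1, B CD45- replicate 2 and B;p38α CD45- replicate 2, at 5.36 in B CD45+ replicate 3 and 6.79 in B CD45- replicate 1, and at 4.30 or less in the remaining arrays. B;p38α CD45+ replicates 1 and 2 were the most alike of all pairs within a group (r = 0.991 across genes).

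The targeted gene was examined first. Mapk14 stood at 10.06 ± 0.11 (SD, n = 5) in B and 9.79 ± 0.20 (SD, n = 3) in B;p38α complete tumors, a difference of -0.27 log2 units (SE 0.15). The two-sided exact permutation p was 0.0714, where 5 against 3 samples can give 0.0357 at the least, and limma's Benjamini-Hochberg adjusted p was 0.807. In CD45+ cells Mapk14 differed by -0.18 (10.39 ± 0.08 against 10.20 ± 0.21, SD, n = 3 each, exact p = 0.3). In CD45- cells, labeled tumor and stroma, it differed by -0.16 (9.79 ± 0.23 against 9.64 ± 0.14, SD, n = 3 each, exact p = 0.4). With 3 against 3 samples the smallest two-sided exact p is 0.1, and limma's adjusted p was 0.672 and 0.803. The 2 groups overlapped in each compartment, although in complete tumors the difference was larger than either SD. Where the array's probes lie relative to the deleted part of Mapk14 is not given in the sources used here, so these levels do not check the labels.

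**Figure D1:**
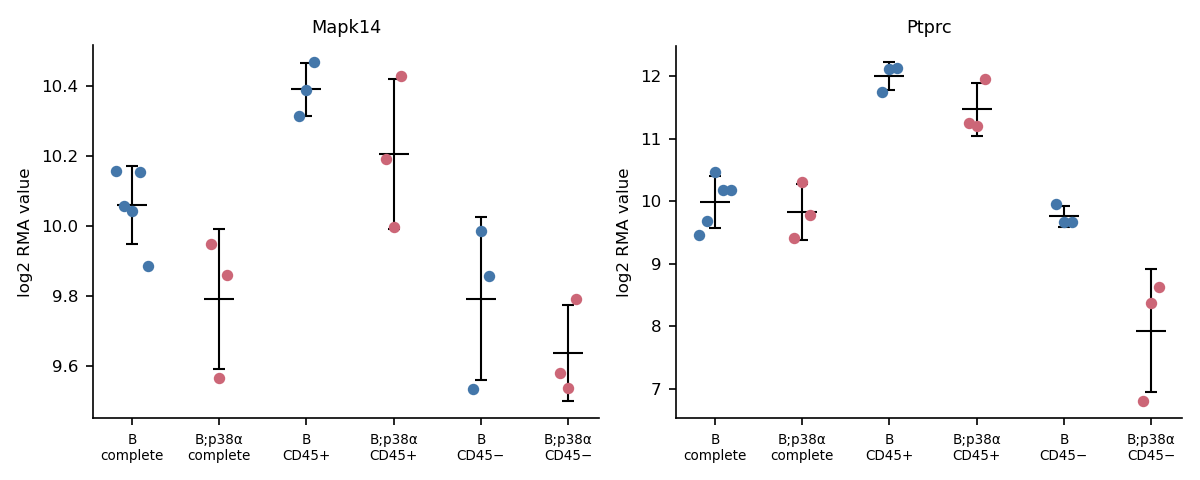
Log2 RMA values of Mapk14 (left) and Ptprc, which encodes CD45 (right), in each of the 20 arrays, by group on the horizontal axis; points are arrays, horizontal marks group means and bars 1 SD. Mapk14 differed between genotypes by -0.27, -0.18 and -0.16 in complete, CD45+ and CD45- samples, and Ptprc was higher in every CD45+ array than in every CD45- array.

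The sort was checked by comparing both CD45+ groups with both CD45- groups. CD45+ cells held higher levels of myeloid genes, led by the macrophage elastase Mmp12 (3.98 log2 units, SE 0.57), Slamf7 (3.58), the endosomal receptor Tlr13 (3.55), the lectin receptors Clec12a (3.51) and Clec4n (3.43), Aif1 (3.50), the inflammasome sensor Nlrp3 (3.41) and Dock2 (3.29). All 17 measured macrophage and monocyte markers rose with the selection, with a median of 2.72, as did 11 of 12 general leukocyte genes (median 2.79), 9 of 10 genes of MHC class II presentation (2.44), 10 of 15 T cell genes (1.06) and 11 of 16 neutrophil genes (1.60). Lower in CD45+ cells were 8 of 23 collagen and matrix genes (median of the list -0.58), 6 of 18 neural crest and dedifferentiated melanoma genes (-0.72, with 2 higher) and 2 of 14 fibroblast genes (-0.58). The 8 genes that fell most were Grik1 (-1.45), Glyat (-1.44), Slitrk1 (-1.32), Brinp1 (-1.31), Lrrn4cl (-1.30), Cntn6 (-1.26), Apba2 (-1.23) and Gria3 (-1.22), several of them best known from neurons. Brinp1 lost its call in 9 and Grik1 in 7 of 12 fits without a single array. Endothelial and pericyte genes went with the leukocytes, 8 of 16 being higher in CD45+ cells (median 1.01). Of the 18 melanocyte pigmentation genes, 2 were higher and 1 was lower in CD45+ cells, and 0 of 17 keratinocyte genes passed. Over all genes 1520 were higher and 852 lower at a limma adjusted p under 0.05. The levels point to a partial separation. In B samples the collagen and matrix list stood at 10.69 in CD45+ and 11.40 in CD45- samples, and the fibroblast list at 10.31 and 11.04. The neural crest list stood at 9.03 and 9.50, and general leukocyte genes at 10.79 and 8.89. Melanocyte pigmentation genes stood at 5.86 and 5.90, so the sort did not separate them as a set.

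Complete tumors were compared between genotypes to ask how loss of p38α in melanocytes altered the whole lesion. Myh4, a myosin heavy chain of fast skeletal muscle, stood at 10.47 ± 0.71 (SD, n = 5) in B and 6.45 ± 2.30 (SD, n = 3) in B;p38α tumors, a difference of -4.03 log2 units (SE 0.83). The kallikrein Klk1b22 (-2.54), the hyaluronan receptor Lyve1 (-2.37) and the secreted WNT modulator Sfrp2 (-2.01) had lower means, with Lyve1 at -1.40 without B;p38α replicate 1, as did the major urinary protein genes Mup9 (-2.40), Mup19 (-2.15), Mup2 (-2.10) and Mup22 (-2.06). Higher means were seen for Rbm46 (2.28), Vxn (1.61), Tafa5 (1.41), Cntn6 (1.35) and the mitotic genes Hjurp, a loader of centromeric histone (1.57), and Pttg1, which encodes securin (1.40). Duxbl2 and Duxbl3 had the same values on the array (1.69 each). They and the Mup genes are near-identical copies whose probes may not tell them apart. None of these 16 genes passed, with limma adjusted p from 0.382 to 0.716. The test called 0 of 19504 genes, with 555 higher and 734 lower at an unadjusted p under 0.05 where 975.2 in all are expected by chance. In 870 genes (4.46%) the groups did not overlap, against 3.57% by chance. Without B replicate 4 the count was 49, and without B replicate 3 it was 2.

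Gene lists fixed from textbook markers before the data were examined moved together more than the remaining genes in 14 of 47 cases by camera with a preset correlation of 0.01, 13 of them downward. Skeletal muscle genes were lower in 17 of 17 members, with a mean difference of -1.64 (list levels 9.88 ± 0.28 and 8.24 ± 2.34, camera adjusted p = 9.19e-08, adjusted p = 0.612 with an estimated correlation). Pvalb (-2.21), Myl1 (-2.15) and Acta1 (-2.03) followed Myh4. This list rested on B;p38α replicate 1: without it the mean was -0.44 (camera adjusted p = 0.0691), and without replicate 3 it was -2.78. Adipocyte genes were lower in 11 of 12 members (mean -1.04, camera adjusted p = 6.75e-06, adjusted p = 0.553 with an estimated correlation), among them the adipokines Adipoq (-2.23), Retn (-1.80) and Lep (-1.70). Macrophage and monocyte markers were lower in 16 of 17 members, with a mean of -0.53 (camera adjusted p = 9.19e-08, adjusted p = 0.546 with an estimated correlation). Among them, the scavenger receptor Cd163 (-1.50), the complement gene C1qc (-0.86) and Adgre1 (-0.83) were 3 of the 4 that passed when adjusted over the list alone, where 0 passed over all genes. Without B;p38α replicate 1 this mean was -0.29 (camera adjusted p = 0.00393). Genes of alternative macrophage activation were lower in 12 of 14 members (mean -0.82, camera adjusted p = 1.94e-06, adjusted p = 0.497 with an estimated correlation). Retnla (-2.69), Folr2 (-1.56) and Stab1 (-1.08) were among 6 adjusted over the list alone, against 0 over all genes.

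General leukocyte genes had a mean of -0.40 in complete tumors (10 of 12 lower, camera adjusted p = 0.000363, adjusted p = 0.612 with an estimated correlation), with Itgb2 (-0.92), Laptm5 (-0.85) and Rac2 (-0.82) passing when adjusted over the list alone and 0 over all genes. Collagen and matrix genes (mean -0.33, 18 of 23 lower, camera adjusted p = 0.000497, adjusted p = 0.676 with an estimated correlation) included Col14a1 (-0.99) and Eln (-0.91). In the fibroblast list (mean -0.40, 10 of 14 lower, camera adjusted p = 0.00803, adjusted p = 0.497 with an estimated correlation) the matrix protein gene Dpt had -1.55. The single list that was higher held NK cell genes (mean 0.56, 7 of 8 higher, camera adjusted p = 0.0103, adjusted p = 0.588 with an estimated correlation), led by the receptors Klrb1c (2.28) and Klra7 (0.97). Its call ended without B replicate 1 (0.40, camera adjusted p = 0.124), without B;p38α replicate 1 (0.52, 0.0597), with dim genes left out (0.55, 0.113) and with the Y-linked covariate (0.54, 0.100). The other 6 lists, all lower, were endothelial and pericyte (mean -0.32), neutrophil (-0.42), hypoxia and glycolysis (-0.23), MHC class I presentation (-0.20), unfolded protein response (-0.21) and NRF2 targets (-0.23). Their adjusted p ran from 0.497 to 0.690 with an estimated correlation. Calls ended without B;p38α replicate 1 for the neutrophil (camera adjusted p = 0.110), hypoxia and unfolded protein lists (0.0597 each), without B;p38α replicate 2 for the endothelial (0.109) and NRF2 lists (0.0681), without B replicate 2 for NRF2 (0.0845), and without B;p38α replicate 3 for MHC class I presentation (-0.03, 0.571). The Y-linked covariate ended those of hypoxia (0.125), unfolded protein response (0.145) and NRF2 (0.0528). MHC class I presentation had -0.31 without B;p38α replicate 2, and endothelial genes -0.19 without B replicate 5. With an estimated correlation 0 of 47 lists passed, the smallest unadjusted p being 0.0174, and fry called 0. Among the components of the p38 pathway, which as a list did not pass, the upstream kinase gene Map2k6 (0.90) was higher, and Hspb1 (-1.25) and Map2k3 (-0.58) were lower when adjusted over the list alone, against 0 over all genes.

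**Figure D2:**
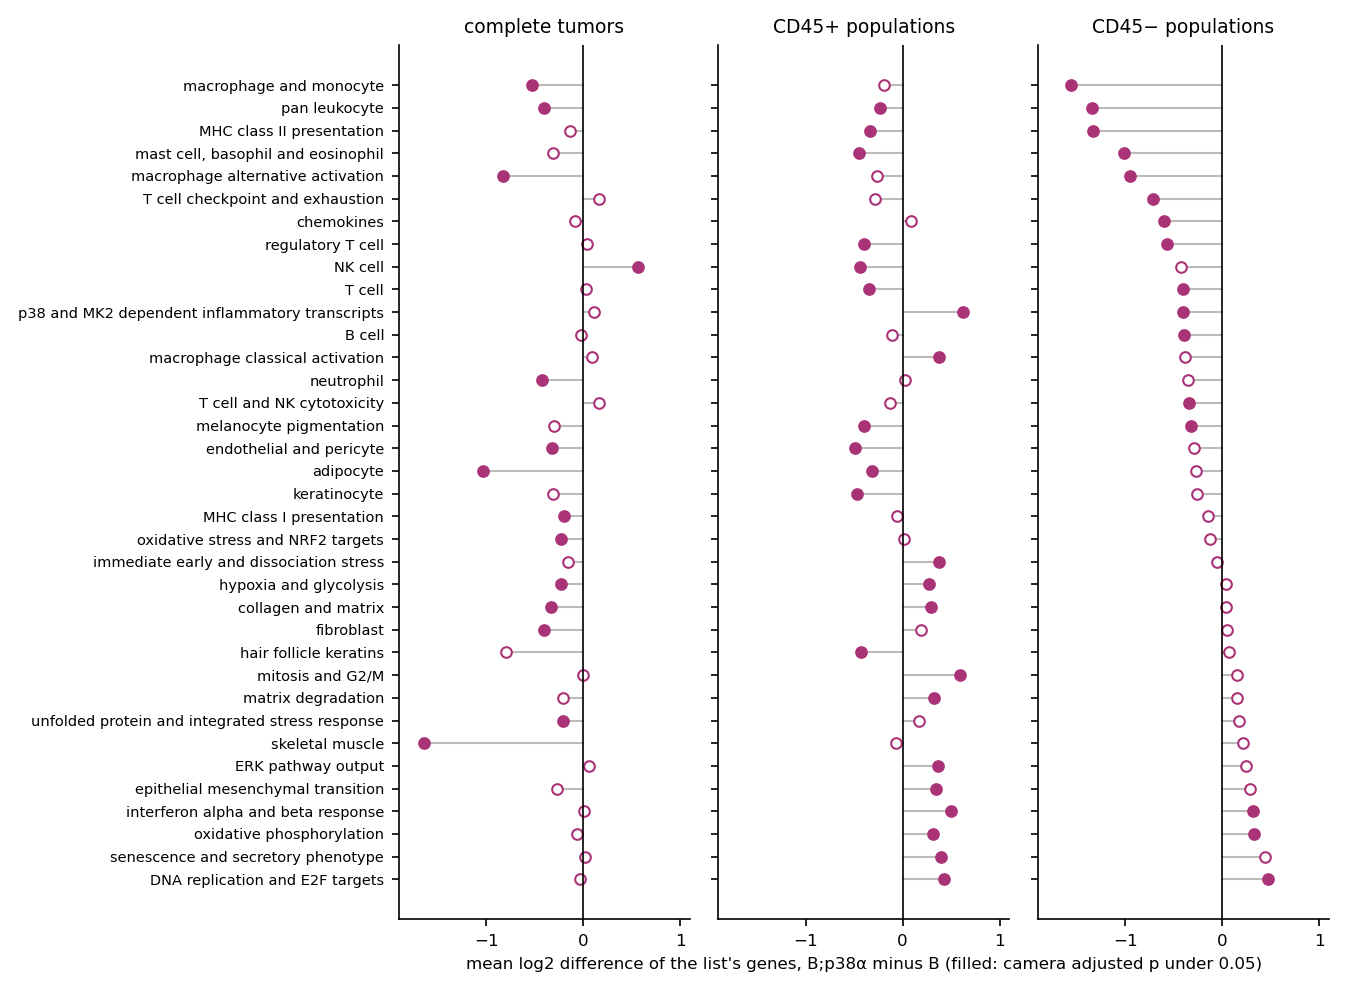
Mean log2 difference, B;p38α minus B, of the genes of each fixed list called in at least 1 compartment, in complete tumors, CD45+ and CD45- populations; filled points mark a camera adjusted p under 0.05 with the preset correlation. The macrophage and monocyte list lay at -0.53, -0.19 and -1.56, and 14, 25 and 16 lists were called, against 0 in each with an estimated correlation.

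CD45+ populations were compared to ask whether the tumor's genotype was reflected in its leukocytes, in which Mapk14 was not targeted. These samples also held stromal and tumor RNA, as the list levels above show, so a difference in them need not be one of leukocytes. The amino acid transporter gene Slc38a4 stood at 5.14 ± 0.44 in B and 9.23 ± 0.70 in B;p38α samples (SD, n = 3 each), 4.09 log2 units higher (SE 0.38). Higher means were also found for the stathmin gene Stmn4 (2.27), Grip1 (2.02), the retinoic acid synthesis gene Aldh1a2 (1.92), Adamts8 (1.92), the neutrophil chemoattractant Cxcl1 (1.89), Maff (1.65) and the imprinted gene Peg3 (1.65). Serpina1b and Serpina1a, copies of the gene of the protease inhibitor alpha-1-antitrypsin, were lower by -4.10 (SE 0.37) and -4.01 (SE 0.40). Mup19 (-3.57), Mup9 (-3.08), Mup22 (-2.93), Mup2 (-2.48), Scrg1 (-2.07) and Aldh1a1 (-2.01) followed. The Serpina1 copies, like the Mup genes, are too alike for their probes to be assigned with certainty. None of these genes passed. Limma's adjusted p was 0.0738 for Slc38a4, Peg3, Serpina1a and Serpina1b, and 0.171 to 0.412 for the remaining genes. The test called 0 of 19504 genes, with 1110 higher and 991 lower at an unadjusted p under 0.05 (975.2 in all by chance), and in 3220 genes (16.5%) the groups did not overlap, against 10% by chance. Without B;p38α replicate 3 the count was 30.

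Of the 47 lists, 13 were higher and 12 lower in B;p38α CD45+ cells by camera. Genes of the interferon alpha and beta response were higher in 23 of 25 members, from a list level of 8.11 ± 0.21 to 8.61 ± 0.18 (SD, n = 3 each), a mean of 0.50 (camera adjusted p = 1.03e-06, adjusted p = 0.575 with an estimated correlation). The antiviral genes Ifit1 (1.15), Bst2 (1.09) and Isg15 (1.04) were among 4 that passed when adjusted over the list alone, against 0 over all genes. With the level of the 3 measured Y-linked genes as a covariate the mean was 0.24 (camera adjusted p = 0.233). These Y-linked genes were lower in B;p38α CD45+ samples by -3.12 on average (camera adjusted p = 0.00435, adjusted p = 0.575 with an estimated correlation), and by -1.84 without B replicate 1. Inflammatory transcripts that depend on p38 and its substrate kinase MK2 were higher in 17 of 20 members (7.83 ± 0.47 against 8.46 ± 0.06, mean 0.63, camera adjusted p = 7.13e-05, adjusted p = 0.575 with an estimated correlation). Cxcl1 (1.89) and the cytokine gene Il6 (1.43) passed when adjusted over the list alone, against 0 over all genes, and Cxcl5 had 1.13 and Cxcl2 1.12. The immediate early and dissociation stress genes, which answer the handling of tissue, moved with them in 22 of 22 members (10.60 ± 0.35 against 10.98 ± 0.14, mean 0.38, camera adjusted p = 0.000115, adjusted p = 0.587 with an estimated correlation), with Socs3 at 0.91 and Fosb at 0.72. Without B replicate 1 that mean was 0.58. The Y-linked covariate raised the inflammatory mean to 1.26 and the immediate early mean to 0.83, and array weights lowered the interferon mean to 0.27.

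Proliferation genes had higher means in B;p38α CD45+ samples. The mitosis list had a mean of 0.59 with 21 of 21 members positive (camera adjusted p = 7.13e-05, adjusted p = 0.587 with an estimated correlation), with Cdk1 at 0.90 and Ttk at 0.86. In B samples the level of the mitosis list was 7.67 ± 0.62 (SD, n = 3), an SD larger than this difference, and members that vary together are not separate evidence. The mean difference was 0.94 without B replicate 1, 0.35 without B replicate 2 and 0.90 without B;p38α replicate 3. The DNA replication list had 0.42 with 20 of 21 positive (camera adjusted p = 1.43e-05, adjusted p = 0.587 with an estimated correlation), with E2f1 at 1.02 and Mcm5 at 0.70, and 0.26 without B replicate 2. Oxidative phosphorylation genes were higher in 22 of 23 members (mean 0.32, camera adjusted p = 1.28e-05, adjusted p = 0.575 with an estimated correlation), including Sdhc (0.61) and Sdha (0.57), subunits of succinate dehydrogenase. Collagen and matrix genes, made mainly by stromal cells, were higher in 20 of 23 (mean 0.30, camera adjusted p = 0.000223, adjusted p = 0.575 with an estimated correlation), and Tnc (1.09) and Col5a2 (0.74) passed adjusted over the list alone, against 0 over all genes. With the Y-linked covariate the collagen mean was 0.14 (camera adjusted p = 0.485). The lists of ERK pathway output (0.36), epithelial mesenchymal transition (0.34), matrix degradation (0.33), hypoxia and glycolysis (0.27), senescence (0.40) and classical macrophage activation (0.37) were also higher, with adjusted p of at least 0.575 with an estimated correlation. Senescence lost its call without B replicate 1 (0.34, camera adjusted p = 0.0862) or B;p38α replicate 3 (0.30, 0.0983), and classical activation without B replicate 2 (0.27, 0.0992), B replicate 3 (0.30, 0.112) or B;p38α replicate 3 (0.31, 0.214). Both lost it with all 6 groups together (0.147 and 0.110) and with dim genes left out (0.161 and 0.353), and senescence also with repeated quantile normalization (0.0645), array weights (0.143) or the Y-linked covariate (0.258). ERK output had 0.23 without B;p38α replicate 1 and 0.58 without replicate 3. The Y-linked covariate raised the means of mitosis (1.501), DNA replication (0.88), oxidative phosphorylation (0.49), ERK output (0.72), epithelial mesenchymal transition (0.53), hypoxia (0.48) and classical activation (0.78), and ended the call of matrix degradation (camera adjusted p = 0.0970). Array weights gave 1.00 for mitosis and 0.63 for ERK output.

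Endothelial and pericyte genes were lower in 15 of 16 members in the same samples (mean -0.49, camera adjusted p = 0.000286, adjusted p = 0.575 with an estimated correlation). The receptor genes Tek (-1.31) and Kdr (-1.02) and the clotting factor gene Vwf (-1.22) had the lowest values, and Vwf passed adjusted over the list alone, with 0 over all genes. The exception was the pericyte channel gene Kcnj8 (1.27). The Y-linked covariate left the mean at -0.49 with a camera adjusted p of 0.0662. T cell genes were lower in 15 of 15 members (mean -0.35, camera adjusted p = 0.00637, adjusted p = 0.587 with an estimated correlation), with Cd3g at -0.71 and Cd8a at -0.62. That call ended without B replicate 2 (-0.20, camera adjusted p = 0.0791), B replicate 3 (-0.25, 0.0622) or B;p38α replicate 1 (-0.24, 0.0543), and the mean was -0.59 without B replicate 1. Melanocyte pigmentation genes were lower in 15 of 18 (mean -0.39, camera adjusted p = 0.00725, adjusted p = 0.575 with an estimated correlation), with the melanin enzyme gene Dct at -1.75 and Gpnmb, which macrophages also express, at -1.19. Without B replicate 2 the mean was -0.24 (camera adjusted p = 0.0560), and without B replicate 1 it was -0.60. With the Y-linked covariate the T cell mean was -0.95 and the melanocyte mean -0.90, and with array weights the T cell mean was -0.63. The remaining lower lists were regulatory T cell (-0.40), NK cell (-0.44), MHC class II presentation (-0.34), mast cell (-0.45), general leukocyte (-0.24), keratinocyte (-0.48), hair keratins (-0.43) and adipocyte genes (-0.32). Their camera adjusted p ran from 0.0176 to 0.0372 (adjusted p from 0.575 to 0.630 with an estimated correlation), and each of these 8 lost its call without some array. Without B replicate 1 the calls of MHC class II (-0.15), general leukocyte (-0.18), mast cell (-0.31) and adipocyte genes (-0.33) ended (camera adjusted p from 0.112 to 0.466), while NK cell (-0.83), keratinocyte (-0.86), hair keratin (-0.67) and regulatory T cell genes (-0.65) had lower means. Without B replicate 2 or 3 those of NK cell (-0.23 and -0.26), keratinocyte (-0.30 and -0.26), hair keratin (-0.31 and -0.32) and regulatory T cell genes (-0.28 in both) ended, as did adipocyte genes without B replicate 2 (0.0510). Without B;p38α replicate 1 or 2 general leukocyte (-0.14 and -0.13), mast cell (-0.25 in both) and NK cell genes (-0.39 and -0.26) lost theirs, and MHC class II without replicate 1 (0.0570). Without B;p38α replicate 3 MHC class II, keratinocyte, hair keratin and adipocyte genes did (camera adjusted p from 0.0634 to 0.195), while mast cell (-0.85), NK cell (-0.67) and general leukocyte genes (-0.44) were lower. The Y-linked covariate gave NK cell genes -1.38, keratinocyte -1.32, regulatory T cell -0.98 and hair keratin genes -0.96, reversed MHC class II (0.16) and ended the calls of general leukocyte (-0.15), mast cell (-0.21) and adipocyte genes (-0.37). Array weights gave NK cell genes -0.94, keratinocyte -0.84, regulatory T cell -0.69 and general leukocyte genes -0.37, and ended the calls of hair keratin (-0.57), MHC class II (-0.20) and adipocyte genes (-0.33). All 6 groups together ended the calls of keratinocyte, hair keratin, adipocyte, general leukocyte and MHC class II genes (camera adjusted p from 0.147 to 0.459). Dim genes left out ended those of hair keratin (-0.18) and NK cell genes (-0.39), with adipocyte genes at -0.55. Repeated quantile normalization ended those of hair keratin, adipocyte and mast cell genes (camera adjusted p from 0.0626 to 0.145), and averaging the 2 most similar arrays, chosen after the data were seen, those of general leukocyte (-0.13), mast cell (-0.25) and NK cell genes (-0.32). In 13 of the 25 lists the call was kept without each single array. With an estimated correlation 0 of 47 lists passed, the smallest unadjusted p being 0.0376, and fry called 2.

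CD45- populations are those that the labels describe as tumor and stroma. In these samples 2 genes differed between genotypes. Slc38a4 rose by 4.92 log2 units in B;p38α cells, from 5.21 ± 0.20 to 10.13 ± 0.50 (SD, n = 3 each, SE 0.30, limma adjusted p = 0.00643). Serpina1a differed by -5.60, from 11.64 ± 0.55 to 6.04 ± 0.06 (SD, n = 3 each, SE 0.30, limma adjusted p = 0.00606). For both genes 3 of 3 B;p38α samples lay beyond all 3 B samples. Serpina1b (-5.53, limma adjusted p = 0.0635), Serpina1e (-3.27, limma adjusted p = 0.114), Mup19 (-4.33), Mup22 (-3.93), Mup9 (-3.45), Mup2 (-3.37) and the parathyroid hormone receptor gene Pth2r (-3.02) had lower means without passing. Higher means that did not pass were those of Aldh1a2 (3.59), the WNT antagonist Dkk2 (2.47), Adgra1 (1.99), the iron regulator Erfe (1.96), Crmp1 (1.91), the neuronal splicing factor Srrm4 (1.88) and Tmeff1 (1.87), each with a limma adjusted p of 0.675. At an unadjusted p under 0.05 there were 682 higher and 637 lower genes (975.2 in all by chance), and in 3113 (15.96%) the groups did not overlap, against 10% by chance. Slc38a4 lost its call without B replicate 2 (limma adjusted p = 0.0829) or replicate 3 (0.0704), with the Y-linked covariate (0.0518), and with all 6 groups fitted together (0.0752), its difference staying between 4.81 and 4.99. Serpina1a lost it without B replicate 3 (0.0704) and with all 6 groups (0.0567), its difference staying at -5.63 and -5.60. Without B;p38α replicate 2 the count was 4.

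Leukocyte transcripts were lower in the B;p38α CD45- cells. The macrophage and monocyte list was lower in 17 of 17 members, from 9.36 ± 0.29 to 7.80 ± 1.20 (SD, n = 3 each), a mean of -1.56 (camera adjusted p = 3.08e-11, adjusted p = 0.5004 with an estimated correlation). The mannose receptor gene Mrc1 (-2.79), the chemokine receptor gene Ccr2 (-2.30), C1qb (-2.11) and Csf1r (-2.08) led it. General leukocyte genes were lower in 11 of 12 members (mean -1.34, camera adjusted p = 6.85e-07, adjusted p = 0.5004 with an estimated correlation), with Cd53 at -2.18 and Ptprc, the CD45 gene, at -1.83. In the MHC class II list (mean -1.33, 9 of 10 lower, camera adjusted p = 9.24e-06, adjusted p = 0.5004 with an estimated correlation) H2-Eb1 (-2.64), H2-Ab1 (-2.22) and Ctss (-2.05) were among 5 that passed adjusted over the list alone, against 0 over all genes. Alternative macrophage activation genes had a mean of -0.95 with 13 of 14 lower (camera adjusted p = 0.000246, adjusted p = 0.5004 with an estimated correlation), with Retnla at -2.17. Chemokine genes were lower in 25 of 32 members (mean -0.59, camera adjusted p = 6.07e-05, adjusted p = 0.5004 with an estimated correlation), including Ccl9 (-2.04) and Ccl12 (-2.03). B;p38α replicate 1 weighed heavily: without it the means were -0.95 for macrophages, -0.72 for general leukocyte genes, -0.79 for MHC class II, -0.51 for alternative activation and -0.37 for chemokines, all with a camera adjusted p under 0.05. Without B;p38α replicate 3 alternative activation had -1.44.

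Mast cell genes were lower as well in the CD45- cells (mean -1.01, 11 of 14 lower, camera adjusted p = 6.07e-05, adjusted p = 0.5004 with an estimated correlation), led by the granule protease genes Cpa3 (-3.39) and Mcpt4 (-2.48), and at -1.54 with dim genes left out. T cell genes were lower in 15 of 15 (mean -0.41, -0.25 without B;p38α replicate 1, camera adjusted p = 0.000653, adjusted p = 0.5004 with an estimated correlation). In the checkpoint list (mean -0.71, 11 of 12 lower, camera adjusted p = 0.000261, adjusted p = 0.5004 with an estimated correlation) Ctla4 (-1.72) and Cd244a (-1.67) were among 3 adjusted over the list alone, with 0 over all genes. B cell genes had a mean of -0.39 (12 of 13 lower, camera adjusted p = 0.00617, adjusted p = 0.5004 with an estimated correlation), and quantile normalization repeated within the comparison ended that call (-0.26, camera adjusted p = 0.105). Oxidative phosphorylation genes were higher in 21 of 23 members (mean 0.33, camera adjusted p = 0.00033, adjusted p = 0.636 with an estimated correlation), again with Sdhc (0.69) and Sdha (0.61), and at 0.17 without B replicate 1, the array of narrow range. DNA replication genes (mean 0.47, 20 of 21 higher, camera adjusted p = 0.00692, adjusted p = 0.688 with an estimated correlation) lost their call without that array (0.12, camera adjusted p = 0.420) and without B;p38α replicate 1 (0.20, camera adjusted p = 0.380), and with dim genes left out (camera adjusted p = 0.0609), and had 0.76 without B replicate 2. Array weights gave 0.09 for DNA replication (camera adjusted p = 0.553), 0.17 for oxidative phosphorylation and -0.25 for T cells. Melanocyte pigmentation genes were lower in 14 of 18 (mean -0.32, camera adjusted p = 0.0138, adjusted p = 0.5004 with an estimated correlation), with Dct at -1.92, Tyrp1 at -1.26 and the melanosomal exchanger Slc24a5 at 1.41. That call ended without B replicate 1 (-0.24, camera adjusted p = 0.0984), and with dim genes left out (-0.20, 0.166), repeated quantile normalization (-0.19, 0.105), array weights (-0.21, 0.0613) or all 6 groups together (0.0820), and the mean was -0.50 without B replicate 2. The regulatory T cell (-0.56), cytotoxicity (-0.34), interferon alpha and beta (0.31) and p38 and MK2 dependent (-0.40) lists were called too, with camera adjusted p from 0.0138 to 0.0440 (adjusted p from 0.5004 to 0.688 with an estimated correlation). Without B replicate 1 all 4 calls ended, with -0.44, -0.23, 0.12 and -0.22 in that order (camera adjusted p from 0.0512 to 0.340). Calls also ended for interferon genes without B replicate 2 (0.24) or B;p38α replicate 3 (0.19), for p38 and MK2 dependent genes without B replicate 2 (-0.32) or B;p38α replicate 2 (-0.18), and for both regulatory T cell and cytotoxicity genes without B replicate 3 (-0.51 and -0.32) or B;p38α replicate 1 (-0.43 and -0.19). Without B replicate 3 the interferon mean was 0.57 and the p38 and MK2 dependent mean -0.66, and the latter was -0.61 without B;p38α replicate 3. Array weights ended all 4 (-0.40, -0.18, 0.18 and -0.36), all 6 groups together the last 3 (camera adjusted p from 0.0520 to 0.0820), dim genes left out the first 3 (-0.37, -0.11 and 0.32), and repeated quantile normalization cytotoxicity (-0.17) and p38 and MK2 dependent genes (-0.39). With an estimated correlation 0 of 47 lists passed, the smallest unadjusted p being 0.0418, and fry called 0. Outside the called lists, the p53 target Phlda3 (1.42) passed adjusted over its list alone, with 0 over all genes.

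**Figure D3:**
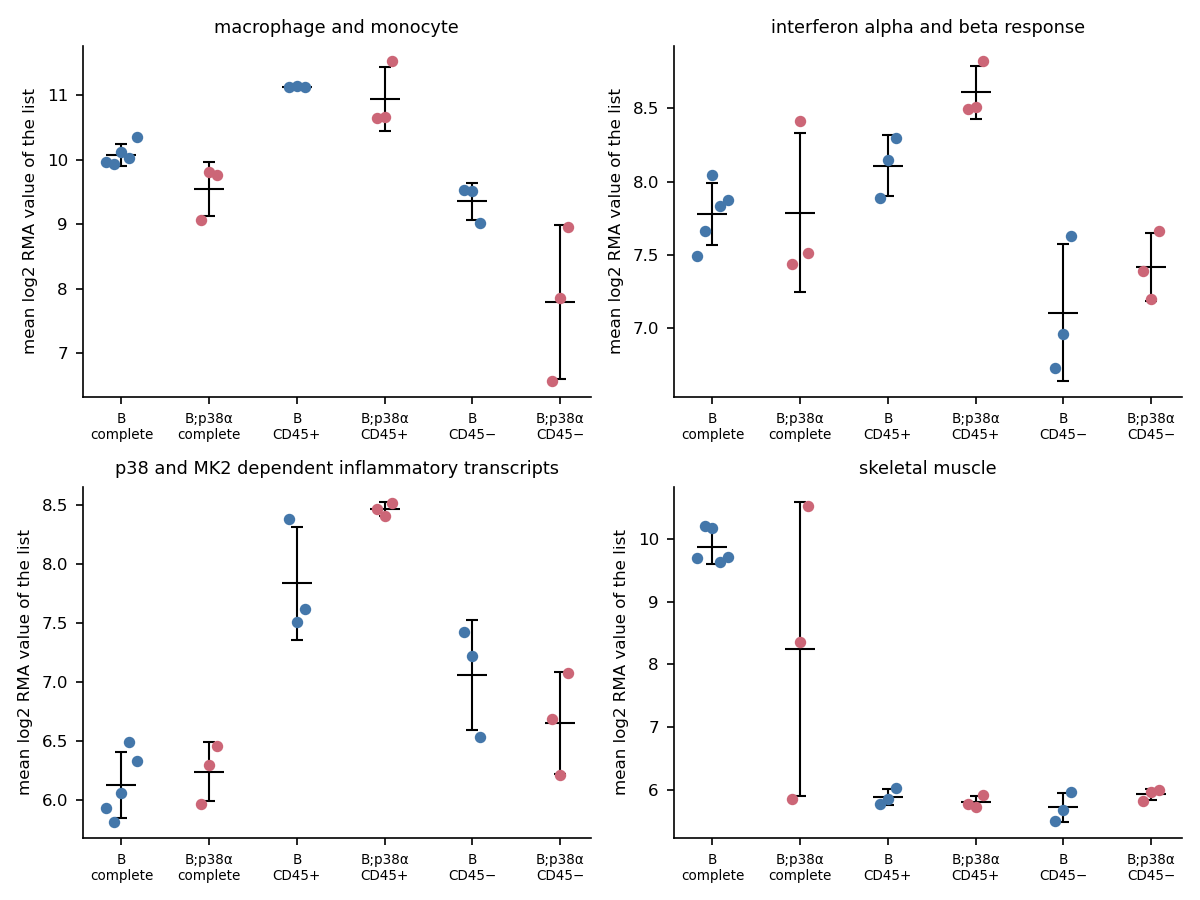
Mean log2 RMA value of 4 fixed lists in each of the 20 arrays, by group on the horizontal axis; points are arrays, horizontal marks group means and bars 1 SD. The macrophage and monocyte list stood at 9.36 ± 0.29 in B and 7.80 ± 1.20 in B;p38α CD45- samples, and the skeletal muscle list spread by an SD of 2.34 in B;p38α complete tumors.

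Whether the genotype difference itself differed between compartments was tested by interaction contrasts in limma. The test called 0 genes between CD45+ and CD45- populations (380 at an unadjusted p under 0.05), 0 between complete tumors and CD45+ populations (1408) and 0 between complete tumors and CD45- populations (1889). Slc38a4 was 4.09 and 4.92 log2 units higher in the B;p38α sorted populations, while in complete tumors its mean was 7.67 ± 1.40 (SD, n = 5) in B and 6.87 ± 2.95 (SD, n = 3) in B;p38α samples. Serpina1a had -3.33 in complete tumors, where B replicate 3 (5.62) lay among the B;p38α samples (5.60 to 6.23), -4.01 in CD45+ and -5.60 in CD45- populations. Across genes, which are not independent replicates, the genotype differences of CD45+ and CD45- populations had a Pearson r of 0.64 and a Spearman rho of 0.61, with the same sign in 71.2% of genes. In 100 relabelings of genotype within each compartment r ran from -0.61 to 0.58, and 0 were as large. The labels do not say whether CD45+ and CD45- samples came from the same tumors, which can raise this r and which the relabelings leave out. A partial separation of the cells, as in the list levels above, can raise r too. A high r therefore need not mean that distinct cell populations differed alike. Without B CD45+ replicate 2 r was 0.49, and 5 of 100 relabelings were as large, as for 0.60 without B;p38α CD45+ replicate 1 or 2. The differences in complete tumors had an r of 0.06 with those in CD45+ and 0.07 with those in CD45- populations, values that 46 and 53 of 100 relabelings matched.

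**Figure D4:**
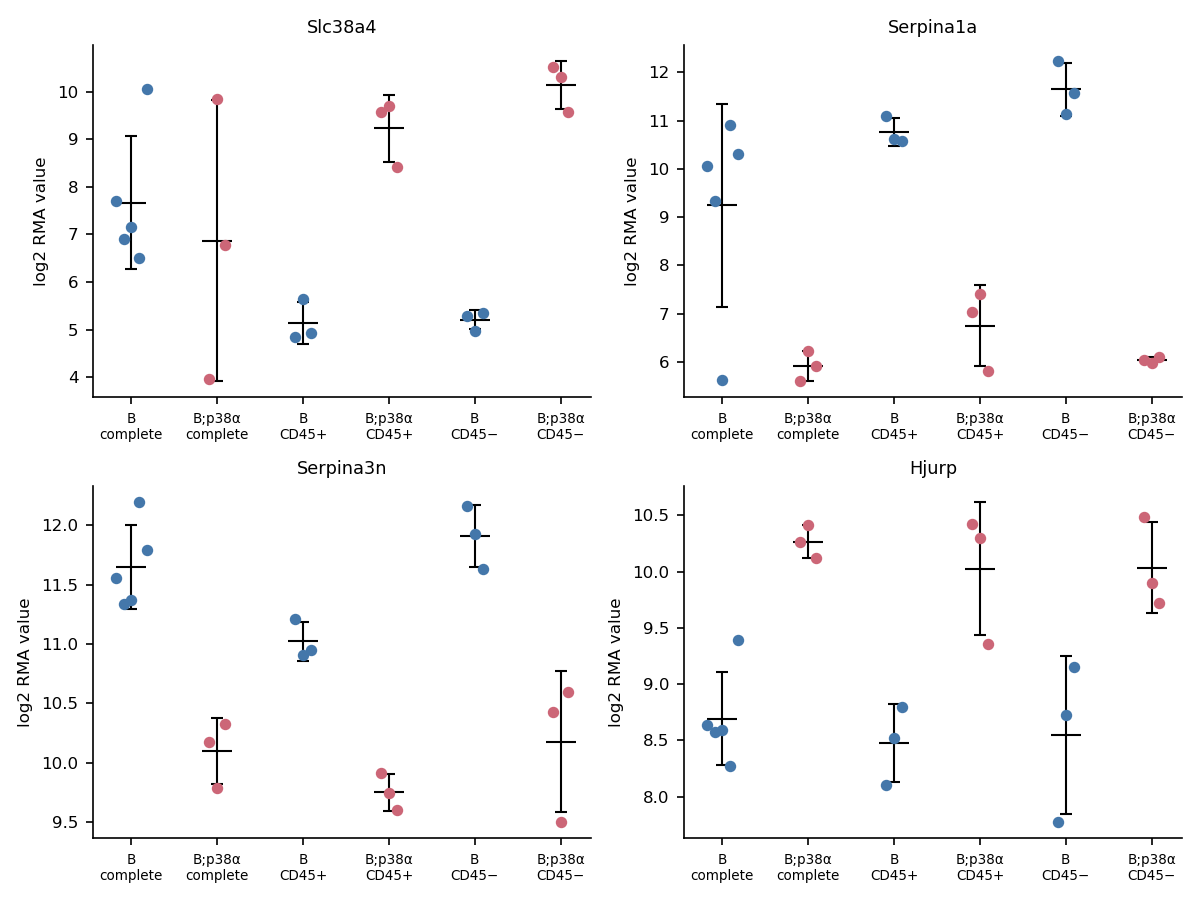
Log2 RMA values of Slc38a4, Serpina1a, Serpina3n and Hjurp in each of the 20 arrays, by group on the horizontal axis; points are arrays, horizontal marks group means and bars 1 SD. Slc38a4 was higher by 4.09 and 4.92 in sorted B;p38α cells and spread widely in complete tumors, and Serpina3n, chosen after its values were seen, was lower by -1.55, -1.27 and -1.73 in complete, CD45+ and CD45- samples.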

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

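The test of distance from the other samples was planned and was applied to the 5 B complete tumors, although Fbln5, a gene of elastic fiber assembly, entered it only through a fit added after the data had been seen. Fbln5 stood at 8.32 in B complete tumor replicate 3 and between 9.49 and 9.86 in the other 4 samples of its group. The gap to the nearest sample was 0.758 of the whole range. The same tumor held Serpina1a at 5.62 (9.33 to 10.91 in the other 4 B tumors), Serpina1b at 2.84 (6.07 to 8.84) and Serpina1e at 4.66 (6.76 to 7.85), each short of the distance tested for. In B;p38α tumors these 3 genes, which lie near Fbln5 on chromosome 12, stood at 5.60 to 6.23, 2.96 to 3.95 and 4.53 to 5.56. Of 43 values tested Fbln5 was the only one so far from its group, where about 1 in 20 groups, or 2.15 of 43, are expected by chance.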

How the results depend on the processing

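The arrays averaged or left out for their similarity or narrow range, and the shared genotype difference over all 3 compartments, were chosen after the data had been seen. The number of arrays limits every count, and how far a signal stood above background was not analysed here. Among named genes, 511 of 603 values under other settings kept direction and side of the threshold, 57 became weaker and 35 stronger, and 732 of 832 did so with an array left out (88 weaker, 12 stronger). Called lists kept both in 348 of 408 camera fits (59 weaker, 1 reversed) and in 300 of 358 with an array left out. With an estimated correlation 0, 0 and 0 lists were called in complete, CD45+ and CD45- samples, and with fry 0, 2 and 0, against 14, 25 and 16. The reversed list was MHC class II presentation in CD45+ populations, 0.16 with the Y-linked covariate. Gene counts in complete tumors, 0 as reported, were 27 with the replicate block and 1 over every row. In CD45+ populations, 0 as reported, they were 2 with all 6 groups, 7 without dim genes, 5303 with array weights, 1 over every row, 250 with the Y-linked covariate and 5 with trended variance. In CD45- populations, 2 as reported, they were 0 with all 6 groups, 4 with array weights and 1 with the Y-linked covariate. Between CD45+ and CD45- populations array weights gave 4275 against 2372. The interaction of complete tumors and CD45+ populations gave 14 with the replicate block and 761 with array weights, and that of complete tumors and CD45- populations 27 with the replicate block, against 0. Over all 3 compartments, 16 as reported, the count was 134 with array weights, 32 over every row, 73 without complete tumors, 3 without CD45- and 1 without CD45+ populations, and 8 with CD45+ and CD45- arrays of a number averaged. Every-row counts add rows without a gene name and second rows of genes; otherwise the cause was not tested. With each array left out, counts ran from 0 to 49 in complete tumors, 0 to 30 in CD45+, 0 to 4 in CD45- and 11 to 86 over all 3 compartments. For the interactions they ran from 0 to 1 between the sorted populations, 0 to 16 for complete tumors and CD45+, and 0 to 37 for complete tumors and CD45-. The similarity of CD45+ and CD45- differences ran from 0.49 to 0.67, and that of complete tumors and CD45- from -0.0138 to 0.146. The replicate numbers are only shared, not a pairing: deviations of same-numbered samples correlated between -0.568 and 0.363, and not every sample correlated best with its own number. The highest values joined different numbers, B CD45+ replicate 1 with B CD45- replicate 2 (0.603) and B CD45+ replicate 2 with B CD45- replicate 1 (0.617), the latter being the 2 arrays of narrowest range, so tumors shared under other numbers are not excluded. With the block 2 genes were called in CD45- populations, Slc38a4 (4.92, limma adjusted p = 0.0591) not among them. The Y-linked list gave no value with its own level as covariate.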

Other observations

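The tests on the genes shared by all 3 compartments, on the leukocyte genes, on the near-identical arrays and on Cxcl1, Il6 and Cxcl5 were chosen only after the results had been seen; the tests of dissociation and of RNA from CD45- cells for the inflammatory list, and the other splits and relabelings, save those over all 3 compartments, were planned. In 9 B;p38α against 11 B arrays, a single genotype difference with compartment as covariate passed in 16 genes (limma adjusted p under 0.05), 5 higher and 11 lower. The acute-phase protease inhibitor gene Serpina3n was lower by -1.52 (SE 0.15, limma adjusted p = 4.9e-05), with -1.55, -1.27 and -1.73 in complete, CD45+ and CD45- samples, and separated all 20 arrays by genotype. Hjurp, which loads centromeric histone, was higher by 1.54 (SE 0.19, limma adjusted p = 0.000527), with 1.57, 1.55 and 1.49. The maintenance DNA methyltransferase gene Dnmt1 (0.85), the stem cell receptor gene Lgr6 (1.39), Map3k13 (0.71) and Nek8 (0.62) were higher as well. Lower were Serpina1a (-4.24), Serpina1b (-4.21), Serpina1e (-2.10), Mup19 (-3.26), Mup9 (-2.93), Mup22 (-2.90), Mup2 (-2.61), the elastic fiber gene Fbln5 (-1.26), Aqp9 (-0.91) and Nabp1 (-0.86). Limma's adjusted p was 0.0497 for Aqp9, Nabp1 and Nek8 and 0.0322 for Lgr6 and Map3k13, and these 5 lost their call in 16, 15, 15, 12 and 11 of 20 fits without an array. In 23 genes the genotypes did not overlap within each compartment in the same direction, where chance gives 1.74 if all arrays are separate and 34.8 if CD45+ and CD45- samples share all their tumors. Sharing of all tumors is argued against, since B;p38α CD45- replicate 2 had a high Y-linked level and no B;p38α CD45+ array did. Sharing of some tumors is left open by the labels. B CD45+ replicate 1 and B CD45- replicate 2 both had a high Y-linked level, and their deviations from the group means correlated at 0.603. Such sharing would also make these p-values too small. Averaging the CD45+ and CD45- arrays of a number gave 8 genes but does not test this, since Y-linked genes differed within number 2 of both genotypes. Eif2s3y stood at 9.55 in B;p38α CD45- and 3.07 in CD45+ samples of that number, and at 9.04 and 5.57 in B. With only 1 sorted population beside the complete tumors, 3 genes passed without CD45- and 1 without CD45+ populations. Serpina3n passed in both (limma adjusted p = 0.00217 and 0.0125), Hjurp only without CD45- populations (0.0109, against 0.0559), and the other 14 of the 16 genes in neither of these fits on fewer arrays.

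A probe set without a gene name here, TC0100003599.mm.2, differed more than any named gene over all arrays, by -5.41 (SE 0.24, limma adjusted p = 5.1e-11 over every probe set). It lay between 7.99 and 10.06 in the 11 B arrays and between 2.95 and 5.04 in the 9 B;p38α arrays. Within compartments its differences were -5.54, -5.03 and -5.61, with limma adjusted p of 0.00061, 0.00414 and 0.0646, and it was singled out after its values had been seen.

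Of the 16 shared genes, 11 kept an adjusted p under 0.05 with the Y-linked level as a covariate, which argues against sex of the animals for most of them; Serpina1e (-1.86 from -2.10), Dnmt1 (0.79 from 0.85), Aqp9 (-0.98 from -0.91), Nabp1 (-0.84 from -0.86) and Nek8 (0.62 in both) did not, at similar sizes and larger SEs (0.13 to 0.37, from 0.12 to 0.34). Variants carried along with the targeted Mapk14 allele are argued against only where they would act on genes beside them, since 0 of the 16 lie on its chromosome. Whether such variants act on genes of other chromosomes was not tested. If the lines differ in genetic background, its effect cannot be told apart from that of genotype, as both would split the animals alike. With the near-identical Mup and Serpina1 copies counted once, the 16 genes make 11 that lie in 9 neighborhoods. Of 10000 random sets of 11 genes, 258 had no more. The Serpina1 copies, Serpina3n and Fbln5 lie near each other. Among these, B complete tumor replicate 3 held Fbln5 at 8.32, near the B;p38α tumors (7.65 to 8.02). It held Serpina3n at 11.37, within the other B tumors (11.34 to 12.19). This neighborhood thus varied within the B line, in 1 tumor, which does not decide the question. For the Serpina1 and Mup genes, RNA of CD45- cells may contribute to the difference in CD45+ samples, though not to that in CD45- samples. Their CD45+ minus CD45- level in B samples had a median of -0.78. In B;p38α samples it was negative for Mup9 (-0.42) and Serpina1b (-0.10). It was positive for Serpina1a (0.71), Serpina1e (0.56), Mup22 (0.48), Mup2 (0.38) and Mup19 (0.19), so this source need not be the whole one. Mup genes stood higher in B complete tumors (Mup9 10.20, Mup19 11.18) than in B CD45- samples (8.62 and 9.35), so where their RNA came from stays open. Nabp1 and Aqp9 were higher in CD45+ cells by 1.51, which argues against RNA of CD45- cells for them. Their differences in CD45- samples (-1.38 and -1.12) lay near the -1.20 of leukocyte genes there. Fewer leukocytes in those samples may therefore contribute for these genes, which was not tested. An effect of p38α loss in melanocytes stays open for all 16 genes. Even so, B complete tumor replicate 3 held Serpina1a (5.62), Serpina1b (2.84) and Serpina1e (4.66) at about the level of B;p38α tumors. Leukocytes were not targeted, so in CD45+ samples such an effect would need RNA of CD45- cells or be indirect. Hjurp and Dnmt1 differed by 1.55 and 0.95 in CD45+ and by 1.49 and 1.02 in CD45- samples. Their CD45+ minus CD45- levels in B samples were -0.08 and -0.01, so neither difference was clearly larger in CD45- samples. The melanocyte pigmentation list stood at 5.86 in B CD45+ and 5.90 in B CD45- samples, so comparing them does not locate an effect in melanocytes.

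Leukocyte genes were lower in B;p38α CD45- populations. The 263 genes at least 2 log2 units higher in CD45+ than in CD45- B samples had a median genotype difference of -1.20 in CD45- populations, 94.3% of them below 0, which is consistent with fewer leukocytes in the CD45- preparations, through the sort or the tumor. Lower expression of these genes by the leukocytes may contribute and is not excluded as the whole cause. Their median in CD45+ cells was -0.31 (-0.56 to -0.18 with an array left out). This range does not overlap that in CD45- cells (-1.51 to -0.76). Such ranges do not measure the spread between samples. The interaction test called 0 genes, but it recovered only 4% of simulated changes of 1 log2 unit, so it decides little here. The median level of these genes was 8.95, 8.95 and 9.80 in B;p38α CD45+ arrays (B 9.38 to 9.66). In CD45- arrays it was 5.12, 6.08 and 6.87 (B 6.99 to 7.51). The genes were chosen on B arrays that also enter these differences, which can bias the CD45+ median downward and the CD45- median upward. The narrow-range B CD45- array is argued against, since the macrophage list had -1.47 without it. Fewer leukocytes in the tumors may contribute, with a median of -0.32 in complete tumors (-0.46 to -0.23 with an array left out). There the arrays overlapped, with median levels of 7.05, 7.51 and 7.28 in B;p38α and 7.24 to 8.17 in B tumors. How far the sort and the tumor's makeup each contribute stays open.

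Inflammatory transcripts that depend on p38 and MK2 were higher in B;p38α CD45+ cells, 0.65 on average in the 18 genes outside the immediate early list (SD over genes 0.57, camera p of 1.34e-05 with the preset correlation; adjusted p = 0.575 with an estimated correlation for the whole list). With the immediate early level of each array as a covariate the mean was 0.20 (SD over genes 0.73, camera p of 0.439, 10 members above 0 against 15), which is consistent with a response of cells to the dissociation, although a covariate fitted to 6 arrays can also absorb a real difference. RNA of CD45- cells is argued against for the list as a whole by a median level 0.82 higher in CD45+ B samples, but stays open for Cxcl1 (-0.73), Il6 (-0.21) and Cxcl5 (-0.60), which were lower there; in B;p38α samples these were higher in CD45+ cells by a median of 0.91, with overlapping arrays. Averaging the near-identical arrays gave the whole list a camera adjusted p of 2.47e-05 with the preset correlation. That test compares genes with genes and depends little on the number of arrays, so it does not decide whether these arrays carry the difference. The mean of the whole list ran from 0.46 to 0.90 with each array left out. The whole list differed by 0.11 in complete tumors, which were not dissociated (camera adjusted p = 0.457), and by -0.40 in the dissociated CD45- populations (-0.18 without B;p38α replicate 2, camera adjusted p = 0.449), where leukocyte genes were lower as well and the immediate early list had a mean of -0.05 and a median of 0.02 (camera adjusted p = 0.656); an effect of the tumor's genotype on its leukocytes stays open.

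Other splits of the samples gave the following. A real count of 0 is matched by any split, so it decides nothing: this holds for genes called in complete tumors (56 of 56 splits, highest other 4), in CD45+ populations (10 of 10, highest other 21) and for the interactions (100 of 100 relabelings each, highest others 37 for the sorted populations, 3 for complete tumors and CD45+, and 7 for complete tumors and CD45-). In complete tumors chance is not excluded: 9 of 56 splits had as many genes at an unadjusted p under 0.05 as the real 1289 (highest other 2374), and 22 of 56 called as many lists as the real 14 (highest other 21). For 3 against 3 samples the 10 splits are too few for a share under 0.05. In CD45+ populations 2 had the real 2101 genes at an unadjusted p under 0.05 (highest other 3516), and 1, the real split, had 25 lists (highest other 22). The split that set B replicate 1 with B;p38α replicates 1 and 2 apart called 21 genes and 22 lists, which points to a structure of these samples other than genotype. In CD45- populations 1 split, the real split, had 2 genes (highest other 0) and 1 had 1319 genes at an unadjusted p under 0.05 (highest other 1212), while 2 had at least 16 lists (highest other 19). Between CD45+ and CD45- populations chance is excluded at 0.05, with 2372 genes against 648 at most in 100 relabelings, of which only the real labeling, 1, was as large. Over all 3 compartments 2 of 100 labelings had at least the real 16 genes. This excludes chance at 0.05 only if no arrays share a tumor, since the labelings treat all 20 as separate, and the highest other had 63, several times as many, which points to a structure of the samples other than genotype.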
